A study of Mus musculus with 24 samples.

How the data were processed

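The libraries came from laser-captured basal forebrain cholinergic neurons of male mice. These neurons were recognised by immunostaining for choline acetyltransferase, the enzyme that makes acetylcholine. The mice were either Ts65Dn, a Down syndrome model that carries an extra copy of part of chromosome 16 and of part of chromosome 17, or disomic littermates (2N). Their dams ate chow with 1.1 g/kg choline chloride (control) or 5.0 g/kg (supplemented), and all offspring ate the control diet after weaning. Total RNA was made into stranded libraries with a low-input kit, 1 library per animal.

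Per the labels, the authors trimmed reads with Trimmomatic 0.39, aligned them with STAR and quantified genes with RSEM. The versions of STAR and RSEM are not given in the sources used here. The labels name the builds GRCm39 and mm10 without the role of each, so no coordinates are given. The deposited series table holds RSEM expected counts per gene with no normalization, and each of its 24 columns equalled the expected counts of the per-sample file. The deposited per-sample files also hold TPM, a length-scaled share of transcripts, which served as an alternative scale for the dosage index. Expected counts were rounded to whole numbers. Of 55414 gene identifiers, 52081 matched a symbol in GENCODE M21, which was used for symbols, chromosomes and gene classes.

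Groups were taken from the genotype and treatment labels. They hold 6 control-diet 2N, 6 control-diet Ts65Dn, 4 supplemented 2N and 8 supplemented Ts65Dn libraries, whereas the design text states 6 per group. Replicate numbers follow the order of the accessions and carry no pairing, so no paired analysis was possible because no label links animals of different groups. The first part of the animal identifier, here called the ID prefix (14 to 17), was examined as a possible batch, although its meaning is not stated. No label gives the litter. All tests treated animals as independent, although the diet was given to the dams, so p-values leave the litter out of account. Total counts ran from 4688258 to 13443438 per library, with a median of 10010353. Reads carried no molecular identifiers, so intervals from counts would cover counting error only, and none is given for the group values, whose error is the spread between animals.

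Genes were kept with the filterByExpr function of edgeR at its minimum count of 10, which left 19967 genes. Libraries were scaled with TMM factors and tested with edgeR's quasi-likelihood F test, with all 24 libraries in 1 fit and no covariate (edgeR 4.0.16, R 4.3.3). Adjusted p-values are Benjamini-Hochberg values over all tested genes, and genes with an adjusted p under 0.05 were called. All tests were two-sided. Log2 fold changes are given with their standard error (SE). A library was counted as higher or lower by its side of the other group's mean log2 CPM. Levels are log2 CPM, the count scaled by library size, with a prior count of 2. The biological coefficient of variation was 1.4. Of 19967 tested genes, 80 had counts identical to those of another tested gene, in 29 sets.

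The named genes followed a rule set before the data were examined: per comparison, up to 12 genes with the smallest p in each direction among those called (6 for the comparison of supplemented Ts65Dn with control-diet 2N and for the interaction). Where fewer were called in a direction, the next smallest p filled up to 5, given as values. Unnamed gene models and pseudogenes were passed over. Up to 4 called members of each list, or otherwise the 2 with the smallest p, and 8 fixed genes, among them Chat, Slc18a3, Slc5a7, Ngfr, App, Sod1 and Dyrk1a, completed the rule. Counts of named genes cover all genes this rule picked, of which 3 are not reported here.

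The 33 gene lists, the comparisons and most alternatives were also fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The fry test asks whether the genes of a list move, on balance, one way; it does not compare them with other genes. List p-values were adjusted over the 33 lists. The lists were 2 of triplicated genes, 20 of neuronal or cellular functions and 11 of cell type markers, of which 10 stood for cells other than neurons of this kind and 1 for neurons in general.

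The dosage index of a library is the mean, over 75 tested triplicated genes of chromosome 16, of log2 CPM centred per gene on the mean of all libraries. Marker scores and list scores were built the same way. Both were compared with exact permutation tests over all splits of the 2 groups, and marker scores were adjusted over 10 lists. Correlations across libraries were taken after subtracting group means, with 1e+05 permutations within groups.

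Alternatives were DESeq2 size factors, a Wald test in DESeq2 1.42.0, limma-voom with quality weights, a robust fit, other filters, thresholds and library sizes, a fit of the compared groups alone, the ID prefix as a factor, a surrogate variable (sva 3.50.0), a glial marker score as covariate, and leaving out each library in turn. Alternatives chosen after seeing the data left out low-complexity libraries or supplemented Ts65Dn 2 and 5, kept 1 ID prefix or protein-coding genes only, and added the mitochondrial rRNA share or a glutamatergic score as covariate. For the dosage index, indices over abundant genes were also chosen after seeing the data, at the 3 floors that were looked at (mean log2 CPM of 5.5, 6 and 6.5).

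The method was tested on simulated data with these library sizes and this spread. Effects were planted only in abundant genes, and genes were drawn independently of each other. The shares recovered therefore hold for abundant genes and may be lower over all tested genes. On the control diet it recovered 3% of genotype effects of 1 on the log2 scale, 53.7% of those of 2 and 83.3% of those of 3. False calls numbered 4 there, 12 beside 104 recovered genes for supplementation in Ts65Dn (10.3% of calls, above the 5% that the threshold aims at), 2 for supplementation in 2N and 5 (5.5%) for genotype on the supplemented diet. Recomputing from the per-sample expected counts was not run, because they equal the series table.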

Results

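RNA was measured in 24 libraries, each from about 500 laser-captured cholinergic neurons of the medial septum and vertical diagonal band of 1 mouse. The groups were 2N on the control diet (n = 6), Ts65Dn on the control diet (n = 6), 2N with maternal choline supplementation (n = 4) and Ts65Dn with supplementation (n = 8), per the labels, whereas the design text states 6 per group. Total counts of control-diet 2N replicates 1 to 6 were 13307831, 9857530, 11001662, 8791793, 7626880 and 10516679. Control-diet Ts65Dn replicates 1 to 6 had 9591709, 10984659, 4688258, 8600576, 11626586 and 8283898. Supplemented 2N replicates 1 to 4 had 13443438, 8232618, 10163176 and 11253071. Supplemented Ts65Dn replicates 1 to 8 had 7761110, 10338723, 10926756, 5917472, 10849440, 5053130, 5097870 and 11255859.

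The libraries differed in quality. RNA of Chat, the gene of the enzyme stained for capture, was under 1 CPM in control-diet Ts65Dn 3, 5 and 6 (0, 0.9 and 0.54). It was also under 1 CPM in control-diet 2N 5 (0.8), supplemented 2N 3 (0.56) and supplemented Ts65Dn 7 (0.57). Its highest value was 54.13 CPM in supplemented 2N 2. The 2 mitochondrial rRNAs took 22.8% ± 2.44 (SD, n = 6) of counts in control-diet 2N and 20.3% ± 6.18 (SD, n = 6) in control-diet Ts65Dn. They took 20.3% ± 1.94 (SD, n = 4) in supplemented 2N and 30.7% ± 8.08 (SD, n = 8) in supplemented Ts65Dn, where replicates 2 and 5 had 17.8% and 21.2%. Control-diet Ts65Dn 3 and supplemented Ts65Dn 7 lay apart on the first principal component (10.2% of variance) and are called low-complexity libraries here, with 13125 and 13164 genes detected. Xist, transcribed from the inactive X chromosome of females, had 237, 155 and 80 counts in control-diet Ts65Dn 1, 2 and 6 and 164 in supplemented 2N 2, with 25 in supplemented Ts65Dn 8, 10 in control-diet Ts65Dn 4 and 0 or 1 in the others, although the mice are described as male. The Y-linked gene Kdm5d had 149, 287, 200 and 279 counts in the first 4 of these and 67 or more in all 24 libraries. The ID prefix was spread unevenly. Control-diet 2N held 2 libraries of prefix 15 and 4 of prefix 17, while control-diet Ts65Dn held 2 of prefix 16 and 4 of prefix 17. Supplemented 2N held 1 of prefix 14, 1 of prefix 15 and 2 of prefix 16. Supplemented Ts65Dn held 1, 4, 2 and 1 of prefixes 14, 15, 16 and 17. The supplementation contrasts therefore also set unlike mixes of prefixes against each other.

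The dosage of the triplicated segment of chromosome 16 was compared first, as a check of the genotype labels. On the supplemented diet the index over 75 triplicated genes rose by 0.55 on the log2 scale in Ts65Dn, a 1.46-fold difference (0.152 ± 0.291, SD, n = 8, against −0.398 ± 0.184, n = 4, exact permutation p = 0.0121, two-sided). On the control diet the index was 0.104 ± 0.395 (SD, n = 6) in Ts65Dn and −0.042 ± 0.239 (n = 6) in 2N, a difference of 0.15 that did not pass (exact permutation p = 0.446). Over the 14 most abundant of these genes, a set chosen after seeing the data, the control-diet difference was 0.38 (exact permutation p = 0.013). The floors of 5.5 and 6.5, also looked at, gave 0.30 and 0.40 (exact permutation p = 0.0346 and 0.0152). By the midpoint between the 2 genotypes (−0.022), 6 of 24 libraries lay on the side of the other genotype: control-diet 2N 1, 3 and 4, control-diet Ts65Dn 3 and supplemented Ts65Dn 5 and 7. The index therefore does not settle the label of a single library. Control-diet Ts65Dn 3 had an index of −0.60, and without it the difference was 0.29 (exact permutation p = 0.0844). Leaving out control-diet Ts65Dn 4 gave 0.05. Within ID prefix 17 the control-diet difference was 0.09 (4 against 4 libraries, exact permutation p = 0.743). Within prefix 16 the supplemented difference was 0.61 (2 against 2, exact permutation p = 0.333, the smallest this design allows). On log2 TPM the differences were 0.01 and −0.10, where the mean over all genes moved by −0.31 on the control diet and −0.38 on the supplemented diet. Relative to all genes, the triplicated genes differed by 0.42 and 0.57 on log2 CPM and by 0.33 and 0.28 on log2 TPM.

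**Figure D1:**
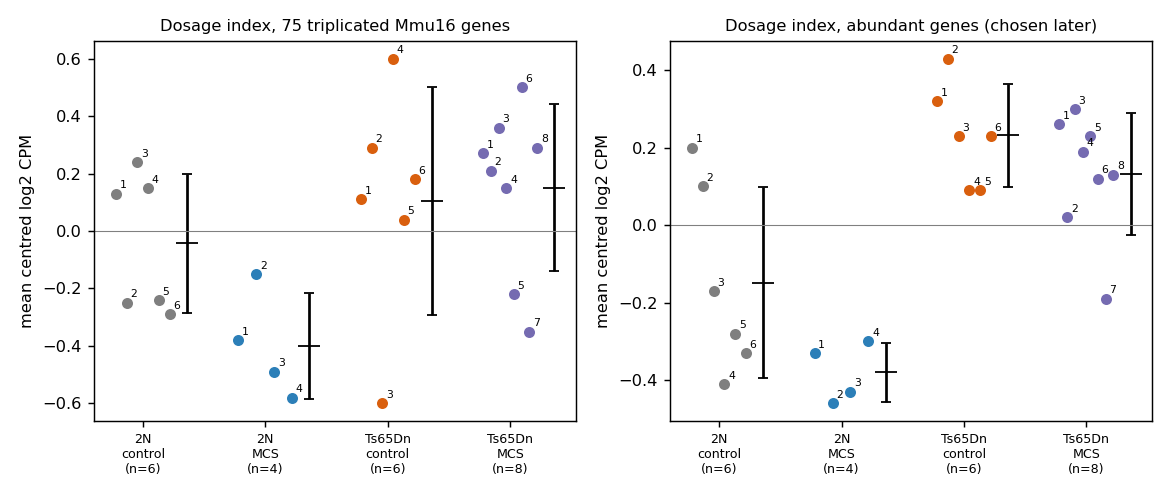
Dosage index of each library (mean of centred log2 CPM) by group, over 75 triplicated genes and over 14 abundant ones chosen later; numbered points are libraries and black bars are mean ± SD. The supplemented groups differ by 0.55 over all 75 genes and the control-diet groups by 0.15.

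The comparison of Ts65Dn with 2N on the control diet asks what trisomy changes in these neurons. Lars2, the mitochondrial leucyl-tRNA synthetase on chromosome 9, rose by 2.51 ± 0.33 on the log2 scale (SE, adjusted p = 2.58e-05). It went from 1258 ± 831 CPM (SD, n = 6) to 7144 ± 3132 CPM (SD, n = 6) and was higher in 6 of 6 libraries. Mir6236 also rose, and a source of reads shared by both genes stays open for this rise. Other genes that rose were Atp2b4, a calcium pump of the cell membrane (1.43 ± 0.27, adjusted p = 0.00786), Camk2a, a calcium-dependent kinase (1.85 ± 0.45, 0.0472), and Gria1, an AMPA receptor subunit (0.95 ± 0.22, 0.0375). Tiam1, a triplicated Rac activator, rose by 1.53 ± 0.33 (adjusted p = 0.0205). Nefm, the medium neurofilament chain, fell by 1.29 (SE 0.30, adjusted p = 0.0411), and Sparc and Sparcl1, which encode secreted matrix proteins, fell by 1.18 and 0.80 (adjusted p = 0.0375 and 0.0472).

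In total 58 genes were higher and 9 lower among 19967 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Protein-coding genes made up 22 of the higher and 8 of the lower ones, small noncoding RNAs 10 of the higher ones, and identifiers outside GENCODE M21 23 of them. Of 23 named genes that passed, 18 lay on the called side of the 2N mean in all 6 Ts65Dn libraries, and the fewest was 4. The other named genes that rose were Mir6236 (2.34), Bc1, a dendritic noncoding RNA (6.87), Plch2, a phospholipase C (2.46), Agap2 (1.32), Cacna1e, an R-type calcium channel (1.63), the small nucleolar RNA Snord55 (6.06), Hivep3 (1.43), Nptxr, the neuronal pentraxin receptor (1.81), and Shank1, a postsynaptic scaffold (0.88). Those that fell were Qk, an RNA-binding protein (−1.14), Ppm1l (−1.49), Cbll1 (−7.17), Tmem184c (−1.99) and Tspyl4 (−1.21). Genes central to cholinergic neurons did not pass singly. Their log2 fold changes were −0.68 for Chat, −1.73 for the vesicular acetylcholine transporter Slc18a3, −2.11 for the choline transporter Slc5a7 and −1.38 for the neurotrophin receptor Ngfr. Slc18a3 was at 0 CPM in control-diet Ts65Dn 2, 3, 4 and 5. Chat was under 1 CPM in control-diet Ts65Dn 3, 5 and 6. Among triplicated genes App was at 0.10, Sod1 at −0.20 and Dyrk1a at 0.79.

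Among the fixed lists, 5 rose and 11 fell of 33. With a glial marker score as a covariate 1 list passed, the astrocyte markers, and the lists of nuclear oxidative phosphorylation, ribosomal proteins, DNA and histone methylation and oligodendrocytes changed direction. The glial score is the mean of the astrocyte and oligodendrocyte scores, so this covariate cannot test either of those lists. The cholinergic list fell, with 17 of 19 genes negative (median −0.89, adjusted p = 0.000117; adjusted p = 0.166 with an estimated correlation) and 1 lower when adjusted over the list alone. Its score was −1.17 ± 1.21 (SD, n = 6) against 0.30 ± 0.36 (n = 6), a difference of −1.47 (exact permutation p = 0.00649), and −1.87 within prefix 17 (exact permutation p = 0.0571). Control-diet Ts65Dn 3 and 5 had the lowest scores, −3.11 and −2.11. Nuclear genes of oxidative phosphorylation fell, with 64 of 74 negative (median −0.59, adjusted p = 9.05e-07; adjusted p = 0.22 with an estimated correlation) and 3 lower when adjusted over the list alone. Mitochondrially encoded mRNAs fell, with 10 of 11 negative (median −0.88, adjusted p = 0.000117; adjusted p = 0.249 with an estimated correlation) and 7 lower when adjusted over the list alone; mt-Co1 was at −1.05. Immediate early genes, which respond to neuronal activity, rose, with 17 of 22 positive (median 1.09, adjusted p = 0.000216; adjusted p = 0.166 with an estimated correlation); Arc was at 1.79, and the highest scores were those of Ts65Dn 3 and 6 (2.39 and 1.90). Glutamate receptor genes rose, with 26 of 37 positive (median 0.28, adjusted p = 0.00226; adjusted p = 0.0961 with an estimated correlation) and 8 higher when adjusted over the list alone.

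The triplicated genes of chromosomes 16 and 17 rose (56 of 75 and 22 of 28 positive, adjusted p = 0.00253 and 0.00391; adjusted p = 0.0961 and 0.079 with an estimated correlation), with 3 and 0 higher when adjusted over the list alone. DNA and histone methylation genes rose (33 of 46 positive, median 0.20, adjusted p = 0.0108; adjusted p = 0.166 with an estimated correlation). Genes of endosomes and lysosomes (41 of 51 negative, median −0.27, adjusted p = 0.00383), the proteasome (30 of 40, −0.38, 0.0108), ribosomal proteins (57 of 79, −0.22, 0.026) and axonal transport (38 of 51, −0.21, 0.0486) fell. In the same order these had adjusted p = 0.249, 0.249, 0.489 and 0.596 with an estimated correlation. The list of choline and one-carbon metabolism, the nutrient pathway supplied by the diet, did not pass (17 of 40 positive, adjusted p = 0.278). The lists of neurotrophin signalling (0.834), synaptic vesicles (0.612), GABA receptors (0.834), voltage-gated channels (0.979), autophagy (0.834), antioxidants (0.314), chaperones (0.128), interferon response (0.463) and Alzheimer-related genes (0.834) did not pass either. Median and mean differed in sign for GABA receptors (0.08 and −0.20), voltage-gated channels (0.02 and −0.20), interferon response (0.32 and −0.09) and Alzheimer-related genes (0.03 and −0.29).

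Markers of other cells moved as well. Astrocyte markers fell (14 of 15 negative, median −0.43, adjusted p = 0.0036; adjusted p = 0.0657 with an estimated correlation), as did those of oligodendrocytes (15 of 15, −0.48, 0.000192; adjusted p = 0.237 with an estimated correlation) and GABAergic neurons (9 of 11, −0.49, 0.0105; adjusted p = 0.0961 with an estimated correlation). Genes shared by neurons fell too (11 of 13, −0.41, 0.0148; adjusted p = 0.418 with an estimated correlation). As scores, astrocyte, oligodendrocyte and GABAergic markers differed by −0.65, −1.23 and −1.02 (exact permutation, adjusted p = 0.0216, 0.0361 and 0.0216), and by −0.72, −1.29 and −1.32 within prefix 17. Glutamatergic markers, which include Camk2a, did not pass (3 of 7 positive, median −0.21, mean 0.50, adjusted p = 0.226). The other marker lists did not pass: oligodendrocyte precursors (0.979), microglia (0.176), vessels (0.892), blood (0.919), ependyma and choroid plexus (0.314) and striatal neurons (0.421), with medians and means of differing sign for precursors (0.06 and −0.38) and vessels (0.17 and −0.27).

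Low-complexity control-diet Ts65Dn 3, whose animal ID is the only one to end in R, a letter of unstated meaning, decided most gene calls: without it 4 genes passed, all among the 67. Of the 23 named calls it ended 20, and Bc1 was then at 1.26, Snord55 at 3.53 and Nptxr at 1.03. The others moved less than 1.5-fold and kept their direction, and over the 12 fits that leave out 1 library Cacna1e ranged from 1.41 to 1.82, Qk from −1.21 to −0.98, Ppm1l from −1.70 to −1.30, Tmem184c from −2.23 to −1.79 and Tspyl4 from −1.30 to −1.05. Without control-diet Ts65Dn 2, Cbll1 was at −8.68. Leaving out control-diet 2N 1 to 6 in turn ended 10, 13, 10, 3, 14 and 8 named calls and left 22, 19, 22, 60, 21 and 35 genes. Leaving out control-diet Ts65Dn 1, 2, 4, 5 and 6 ended 4, 1, 0, 6 and 8 and left 77, 117, 127, 60 and 43 genes. Lars2 (2.25 to 2.78), Mir6236 (2.16 to 2.57) and Atp2b4 (1.29 to 1.52) passed in all 12 of these fits. The ribosomal list was lost without control-diet Ts65Dn 3 or 5 or control-diet 2N 3 or 4 (adjusted p = 0.47, 0.0547, 0.0773 and 0.0686). The axonal transport list was lost in 7 of the 12 fits: without control-diet 2N 1, 2, 5 or 6 (0.167, 0.111, 0.0623 and 0.143) and without Ts65Dn 4, 5 or 6 (0.0809, 0.123 and 0.334). Without Ts65Dn 5 the methylation, proteasome and shared neuronal lists were lost (0.0542, 0.057 and 0.0637), and without Ts65Dn 6 the shared neuronal list (0.0656). Within ID prefix 17 edgeR called 0 genes (915 of 13991 at an unadjusted p under 0.05), with Lars2 at 2.46, and with the prefix as a factor 28, of which 24 were among the 67. With a glial marker score as a covariate 1 gene passed, and 0 of the 67. The robust fit gave 22 genes, a surrogate variable 2 and a fit of these 2 groups alone 3, whereas the mitochondrial rRNA share as a covariate, chosen after seeing the data, gave 162. Over all libraries, 2179 genes had an unadjusted p under 0.05, DESeq2 called 459 genes and limma-voom 3. An exact 5% of the tested genes would be 998. Simulated genes without an effect passed at 6%, and such counts were not taken over other splits, so the excess due to genotype is not known.

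**Figure D2:**
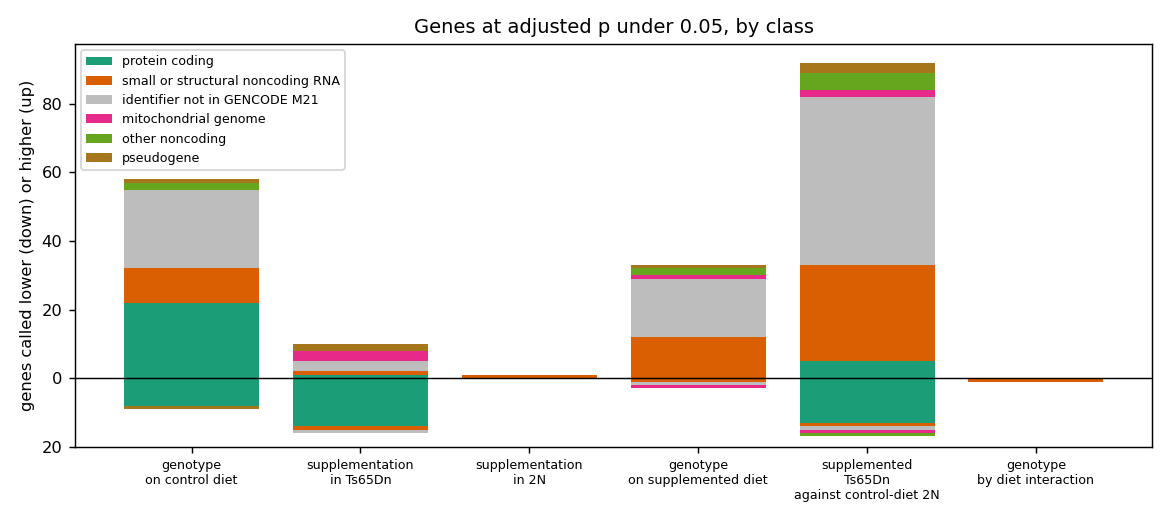
Number of genes with an adjusted p under 0.05 in each of the 6 comparisons, higher ones drawn upward and lower ones downward, coloured by gene class. Control-diet Ts65Dn against 2N gave 58 higher and 9 lower genes, and supplemented Ts65Dn against supplemented 2N 33 and 3, of which 0 were protein-coding.

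Supplemented and control-diet Ts65Dn mice were compared to ask what the maternal diet changes in trisomic neurons. Genes that fell were Nptxr (by 2.88, SE 0.38, adjusted p = 2.71e-05), Enc1, an actin-binding protein (by 2.40, SE 0.40, 0.00164), Camk2a (by 1.98, SE 0.41, 0.0212), and Chgb, a secretory granule protein (from 451 ± 118 CPM, SD, n = 6, to 225 ± 50.4 CPM, SD, n = 8, adjusted p = 0.0154). Each was below the control-diet mean in 8 of 8 supplemented libraries, and below every control-diet library in 6 for Nptxr and Enc1, 5 for Camk2a and 8 for Chgb. Hpcal4, a calcium sensor, fell by 2.06 (0.0212), and the NMDA receptor subunit Grin2a and the vesicle protein Sv2b by 1.37 and 3.29 (both 0.0464). Mitochondrially encoded mt-Nd1 and mt-Nd6, subunits of complex I, rose by 1.37 ± 0.29 and 1.15 ± 0.24 (SE, both 0.0212) and were higher in 8 of 8. Rprl2, a gene resembling the RNA of ribonuclease P, rose by 9.27 ± 1.48 (0.000876, 5 of 8).

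In total 10 genes were higher and 16 lower (edgeR), and 14 of the lower ones were protein-coding. The mt-Atp6 gene, another mitochondrial subunit, had 0 counts in all 6 control-diet Ts65Dn libraries and was above 0 in 5 of 8 supplemented ones, at least 6380-fold higher against a floor of 3 counts over the group (adjusted p = 0.00172). Supplemented Ts65Dn 7, at 3508 CPM where the other 7 had 0 to 504, carries much of this, and without it the bound was 2810-fold. In the control-diet libraries mt-Atp8, which shares a transcript with mt-Atp6, averaged 399 CPM, so the 0 cannot be read as absent expression. Cbll1 rose by 6.66 (0.0464), and Kif3a, a kinesin motor (−0.99), Cacna1e (−1.37), Ddn, a dendritic protein (−2.36), and Adcy1, an adenylyl cyclase (−1.39), fell. Of the 17 named calls, 15 lay on the called side of the control-diet mean in 8 of 8 libraries. Below every control-diet library were 4 of 8 for Hpcal4, 3 for Sv2b and Cacna1e, 2 for Ddn and 1 for Adcy1. Genes of the cholinergic type did not pass singly, with Chat at 0.93, Slc18a3 at 3.14, Slc5a7 at 1.84, and Ngfr 2.83-fold higher. App was at −0.15, Sod1 at 0.61 and Dyrk1a at −0.39.

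Of the lists, 3 rose and 4 fell. With a glial marker score as a covariate 2 lists passed, mitochondrially encoded genes and ribosomal proteins, and oligodendrocyte markers changed direction. The cholinergic list rose, with 16 of 19 positive (median 1.19, adjusted p = 1.16e-06; adjusted p = 0.159 with an estimated correlation) and 0 higher when adjusted over the list alone. Its score differed by 1.56 (0.38 ± 0.59, SD, n = 8, against −1.17 ± 1.21, n = 6, exact permutation p = 0.002), and by 0.49 within prefix 16 (2 against 2 libraries). Mitochondrially encoded genes rose (10 of 11, median 0.98, 2.71e-08; adjusted p = 0.187 with an estimated correlation), 9 of them when adjusted over the list alone, in a group where the mitochondrial rRNA share was also higher. Immediate early genes fell (20 of 22 negative, median −1.33, 9.45e-08; adjusted p = 0.159 with an estimated correlation), as did glutamate receptors (27 of 37, −0.33, 0.0039; adjusted p = 0.159 with an estimated correlation), with 5 and 8 lower when adjusted over the list alone. Ribosomal proteins fell (53 of 79, −0.27, 0.0195; adjusted p = 0.509 with an estimated correlation). Oligodendrocyte markers rose (13 of 15, 0.75, 0.00018; adjusted p = 0.334 with an estimated correlation) and glutamatergic markers fell (6 of 7, −1.98, 0.035; adjusted p = 0.295 with an estimated correlation). As scores these 2 differed by 0.96 and −1.25 and did not pass (exact permutation, adjusted p = 0.107 and 0.117).

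Without both low-complexity libraries, an alternative chosen after seeing the data, 77 genes passed, 20 of them among the 26, and the glutamatergic list was lost. Leaving out supplemented Ts65Dn 1 to 8 in turn ended 10, 5, 7, 8, 4, 11, 2 and 1 of the 17 named calls and left 14, 33, 19, 16, 34, 12, 35 and 36 genes. Leaving out control-diet Ts65Dn 1 to 6 ended 5, 0, 5, 1, 9 and 12 and left 22, 36, 80, 57, 16 and 13. Rprl2, mt-Atp6, Nptxr (−3.11 to −2.10) and Enc1 (−2.60 to −1.63) passed in all 14 of these fits. Without control-diet Ts65Dn 3, Nptxr was at −2.10 and Enc1 at −1.63, and Hpcal4 (−1.42) and Ddn (−1.37) no longer passed. Rprl2 was at 11.13 without control-diet Ts65Dn 6, and Cbll1 at 8.17 without control-diet Ts65Dn 2. The ribosomal list was lost without supplemented 1 or 6 (adjusted p = 0.0657 and 0.0824) or control-diet 1, 2 or 4 (0.15, 0.111 and 0.0748). The glutamatergic list was lost without supplemented 1 or 6 (0.0828 and 0.0646) or control-diet 3, 5 or 6 (0.118, 0.067 and 0.12), and 11 lists passed without supplemented 8. Within ID prefix 16 (2 against 2 libraries) 103 genes passed, 6 of them shared; Nptxr was at −1.47 and Camk2a at −0.16. With the prefix as a factor 15 passed, 12 of them shared, and with a glial marker score as a covariate 36, of which 4 were shared. The robust fit gave 13 genes, a surrogate variable 87 and a fit of these 2 groups alone 6. Leaving out supplemented Ts65Dn 2 and 5 gave 69 and the mitochondrial rRNA share as a covariate 59, both chosen after seeing the data. DESeq2 called 349 genes and limma-voom 4.

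Both comparisons share the control-diet Ts65Dn libraries with opposite sign. Across 19967 genes, which are not independent replicates, the log2 fold changes of genotype and of supplementation in Ts65Dn had r = −0.50. Simulated groups without any effect gave −0.53 on average (−0.68 to −0.36). With the shared libraries split 3 and 3, the mean r was −0.04 (−0.11 to 0.04 over 20 splits). Opposition across all genes was therefore not detectable beyond the shared libraries. Of the genes called in both, 4 were higher in Ts65Dn and lower with supplementation and 2 the reverse. Simulations gave 0 and splits a mean of 1 and 0.1. The simulations held no effect, so an overlap near 0 was fixed in advance, and the splits left fewer libraries to call genes with. Neither shows what overlap the shared libraries alone would give.

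In 2N mice the same contrast asks what the diet changes without trisomy. Mir6236, annotated as a microRNA, rose by 2.17 ± 0.35 (SE, adjusted p = 0.00413), from 348 ± 160 CPM (SD, n = 6) to 1568 ± 591 CPM (SD, n = 4), and was higher in 4 of 4 supplemented libraries. It was the 1 gene called by edgeR, with 1382 genes at an unadjusted p under 0.05, 286 called by DESeq2 and 7 by limma-voom. Lars2 was at 1.49 (adjusted p = 0.52), Klhl36 at 5.92, St18 at −3.72, Mapk7 at −3.53, Pex3 at −6.30 and Cdr1 at −0.91. Among fixed genes App was at −0.40 and Ngfr 2.38-fold higher. Whether Mir6236 and Lars2 share a source of reads was not tested for the rise of Mir6236.

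None of the 33 lists passed with camera in 2N mice: 0 were called, and the smallest adjusted p was 0.0786 for mitochondrially encoded genes (10 of 11 negative, median −0.58). The cholinergic list had 15 of 19 positive (median 0.32), and its score differed by 0.24 (exact permutation p = 0.505). GABAergic marker scores differed by −0.68 (exact permutation, adjusted p = 0.0476). Without supplemented 2N 1, Mir6236 was at 1.89 and 0 genes passed in edgeR (1465 at an unadjusted p under 0.05), and 1 list passed without supplemented 2N 1 or 3 or control-diet 2N 6. The robust fit in edgeR gave 0 genes (1369 at an unadjusted p under 0.05). Without supplemented 2N 2 or 3 or control-diet 2N 6, 2 genes passed. With the ID prefix as a factor 1 gene passed, not Mir6236, and no prefix held 2 libraries of both groups.

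Among supplemented mice, Ts65Dn was compared with 2N to ask which genotype differences are present under the diet. Of the 36 genes that passed, 18 were identifiers outside GENCODE M21 and 13 small noncoding RNAs. Bc1 rose by 7.81 ± 1.55 (SE, adjusted p = 0.0229, 7 of 8 libraries), Snord55 by 8.20 ± 1.70 (0.0229, 8 of 8), Snord22 by 6.99 (0.0298, 8 of 8) and Rprl2 by 9.82 ± 1.83 (0.0193, 5 of 8). For Snord55 this count includes supplemented Ts65Dn 2 and 5, both at 0.34 CPM, barely above the highest supplemented 2N library (0.29 CPM). The other supplemented Ts65Dn libraries had 19.84 to 105.82 CPM of Snord55. Snora74a and Snora81 had 0 counts in all 4 supplemented 2N libraries and were at least 1050-fold and 457-fold higher (floor of 3 counts over the group, adjusted p = 0.0229 and 0.038), or 688-fold for Snora74a without supplemented Ts65Dn 1. Snord15a and Snord21 rose by 6.13 and 9.22, and the mitochondrial rRNA mt-Rnr2 by 1.08 ± 0.25 (0.0448, 7 of 8), while the mitochondrial tRNA mt-Tq fell by 2.29 (SE 0.53, 0.0448, 8 of 8).

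In total 33 genes were higher and 3 lower (edgeR), of which small noncoding RNAs made up 12 and 1; the median over 226 of them was 4.18. Protein-coding genes numbered 0, with 933 of 14419 at an unadjusted p under 0.05 when these were tested alone. Tpt1 was at −1.53, Kif3a at −0.90 and Ubb at −0.90. Genes fixed beforehand were at −0.71 for Chat, −0.06 for Slc18a3, −0.44 for Slc5a7, −1.13 for Ngfr, 0.34 for App, 0.52 for Sod1 and 0.23 for Dyrk1a. Triplicated genes of chromosomes 16 and 17 rose (60 of 75 and 23 of 28 positive, medians 0.60 and 0.60, adjusted p = 3.86e-06 and 0.000151), and both calls held with an estimated correlation (adjusted p = 0.0093 for each with an estimated correlation). Adjusted over the list alone, 3 and 4 were higher; Paxbp1 was at 1.32 and Son at 0.75. Chaperone genes fell (30 of 32 negative, median −0.41, 4.51e-05; adjusted p = 0.207 with an estimated correlation). Nuclear oxidative phosphorylation (53 of 74, −0.37, 3.28e-05) and ribosomal protein genes (47 of 79, −0.34, 0.000215) fell, and mitochondrially encoded genes rose (10 of 11, 0.85, 0.000151), each with adjusted p = 0.489 with an estimated correlation. The cholinergic score differed by −0.16 (exact permutation p = 0.691), and no other cell marker score passed (smallest adjusted p = 0.621, exact permutation).

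The supplemented 2N group is small. Leaving out supplemented 2N 1 to 4 in turn ended 10, 9, 10 and 9 of the 10 named calls and left 0 (1802 at an unadjusted p under 0.05, edgeR), 5, 1 and 3 genes. Without supplemented 2N 1, Snord55 was at 9.07 and Snord21 at 11.07, and without supplemented 2N 4 Rprl2 was at 13.84. Leaving out supplemented Ts65Dn 1, 3, 6, 7 and 8 ended 5, 3, 6, 3 and 4 named calls and left 16, 29, 15, 27 and 19 genes. Without supplemented Ts65Dn 2 or 5, whose mitochondrial rRNA share is low, 72 and 71 genes passed, and 150 without both. With the mitochondrial rRNA share as a covariate, an alternative chosen after seeing the data, 0 passed in edgeR (1158 at an unadjusted p under 0.05). Within ID prefix 16 (2 against 2 libraries) 92 passed, 34 of them shared, and with the prefix as a factor 40. The robust fit in edgeR gave 0 (1867 at an unadjusted p under 0.05), a surrogate variable 15 and a fit of these 2 groups alone 91. DESeq2 called 542 genes and limma-voom 55.

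**Figure D3:**
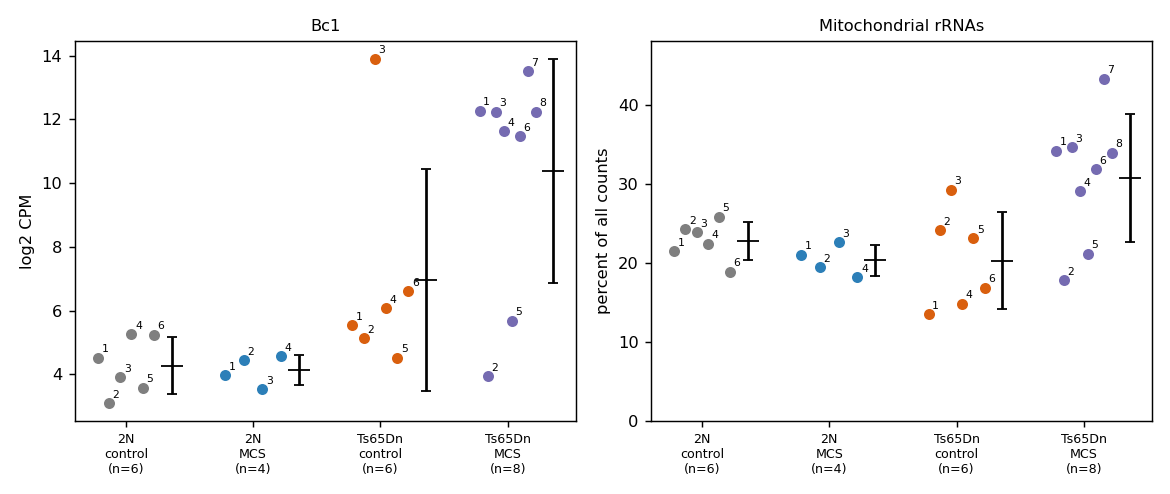
Log2 CPM of Bc1 (left) and percent of counts in the mitochondrial rRNAs (right) in each library, by group; numbered points are libraries and black bars are mean ± SD. In 7 libraries Bc1 lies between 11.47 and 13.91 log2 CPM and in the other 17 between 3.09 and 6.61.

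Supplemented Ts65Dn was also set against control-diet 2N, which shows what separates supplemented trisomic from untreated disomic mice. Lars2 rose by 2.69 ± 0.32 (SE, adjusted p = 2.14e-06, 8 of 8 libraries), Snhg14, a long noncoding RNA that hosts small nucleolar RNAs, by 0.96 ± 0.16 (0.000688, 8 of 8), Bc1 by 7.50 ± 1.26 (0.000568, 7 of 8) and Snord15a by 6.11 ± 1.05 (0.000763, 7 of 8). Rprl2 rose by 9.43 ± 1.48 (0.000286, 5 of 8), and mt-Atp6, at 0 in all 6 control-diet 2N libraries, was at least 7210-fold higher (0.000688), or 3180-fold without supplemented Ts65Dn 7. Here too the 0 cannot be read as absent expression, since mt-Atp8 averaged 1082 CPM in control-diet 2N. Rprl2 was at 10.13 without control-diet 2N 5. Chgb fell by 1.01 (0.00376), mt-Tq by 2.36 (0.00686), Tpt1 by 1.52 (0.01), Ubb, a ubiquitin gene, by 0.93 (0.0138), Kif3a by 0.90 (0.0165) and Ubxn4 by 1.28 (0.0177), each lower in 8 of 8. In total 92 genes were higher and 17 lower (edgeR), 49 of the higher ones identifiers outside GENCODE M21 and 28 small noncoding RNAs. Of the higher ones, 37 were also higher in control-diet Ts65Dn, a comparison with the same control-diet 2N libraries. Simulations without any effect gave a mean of 0.05, and with the shared libraries split the mean was 1 and the highest 1. With no effect planted, an overlap near 0 was fixed in advance, and the splits left fewer libraries to call genes with. Neither shows what overlap the shared libraries alone would give, so no conclusion is drawn from the 37. The triplicated genes of chromosome 16 rose (53 of 75 positive, median 0.31, adjusted p = 0.00974; adjusted p = 0.351 with an estimated correlation). Ribosomal protein genes (57 of 79 negative, −0.49, 1.77e-06), nuclear oxidative phosphorylation (49 of 74, −0.32, 0.00196), chaperones (22 of 32, −0.33, 0.00499) and axonal transport (37 of 51, −0.16, 0.041) fell. These had adjusted p = 0.351, 0.557, 0.452 and 0.675 with an estimated correlation, and 8, 1, 2 and 4 genes were lower when adjusted over the list alone. With the ID prefix as a factor 148 genes passed, 101 of them shared, while DESeq2 called 470 genes and limma-voom 302. The robust fit gave 36 genes, a surrogate variable 52 and a glial marker score as a covariate 61. Chosen after seeing the data, leaving out supplemented Ts65Dn 2 and 5 gave 228 and the mitochondrial rRNA share as a covariate 28. Leaving out control-diet 2N 4, 5 or 6 ended the calls of Tpt1 (−1.34), Ubxn4 (−1.21), and both Ubb (−0.88) and Ubxn4 (−1.23).

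**Figure D4:**
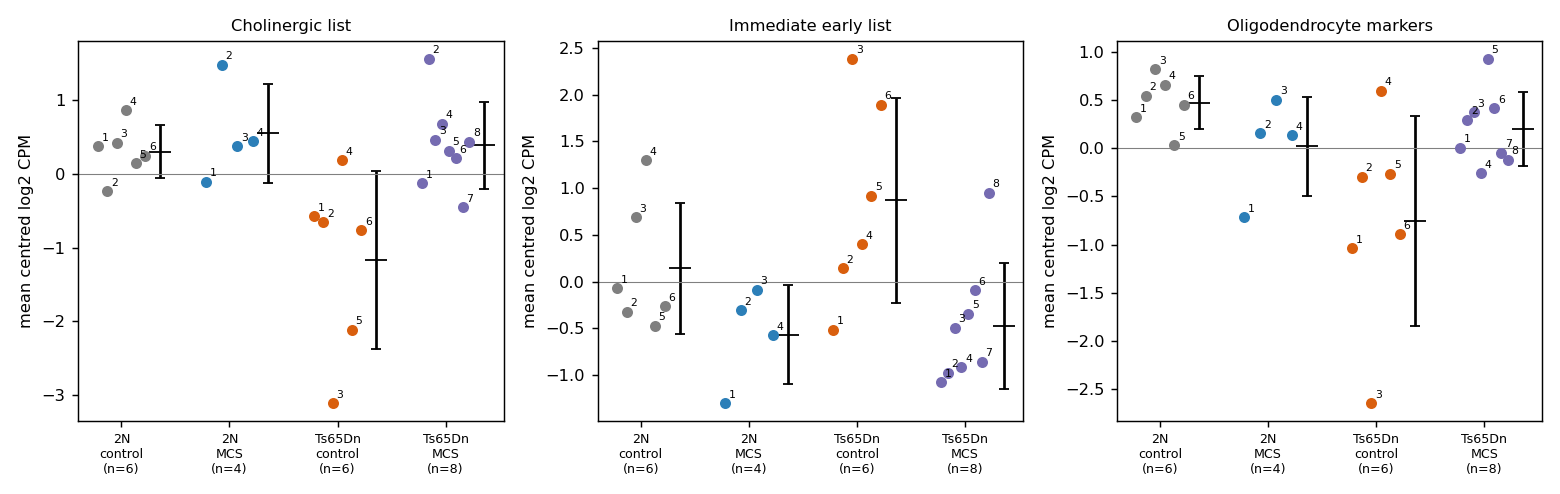
Scores of the cholinergic, immediate early and oligodendrocyte lists (mean centred log2 CPM) in each library by group; numbered points are libraries and black bars are mean ± SD. The cholinergic score averages −1.17 in control-diet Ts65Dn and 0.38 in supplemented Ts65Dn.

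Whether the diet contrast differs between genotypes was tested as an interaction. Mir6236 differed, with a supplementation contrast of −0.89 in Ts65Dn and 2.17 in 2N (difference −3.06, SE 0.46, adjusted p = 0.000705), and passed without each of the 24 libraries in turn (−3.29 to −2.78). No other gene passed: mt-Nd1 was at 1.95 and Nptxr at −2.30 (adjusted p = 0.158 and 0.193), so a diet effect specific to Ts65Dn was not shown for these genes. Of the lists, cholinergic genes (13 of 19 positive, median 0.94, adjusted p = 0.0432; adjusted p = 0.565 with an estimated correlation), mitochondrially encoded genes (11 of 11, 1.54, 2.82e-09; adjusted p = 0.419 with an estimated correlation) and oligodendrocyte markers (14 of 15, 1.12, 0.000202; adjusted p = 0.419 with an estimated correlation) rose more, or fell less, in Ts65Dn. Mir6236 was the 1 gene called by edgeR, with 1683 at an unadjusted p under 0.05; DESeq2 called 366 and limma-voom 0. With the ID prefix as a factor 12 passed, Mir6236 among them. The call of Mir6236 ended in the robust fit in edgeR (adjusted p = 0.168), in limma-voom (−3.29, adjusted p = 0.0606) and with the mitochondrial rRNA share as a covariate (−2.49, adjusted p = 0.0677), chosen after seeing the data. The robust fit and this covariate gave 0 genes, with 1687 and 1753 at an unadjusted p under 0.05. Of 100 splits of the libraries, the real one included, 14 gave as many genes, so chance cannot be excluded.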

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

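Tests of trisomy, of the low-complexity libraries, of glial RNA and of all explanations for the mitochondrial rRNA share were chosen after the results were seen. Of 256 groups of values, 13 held a library far from the rest, where the 95% limit used flags about 1 in 20 groups of normally spread values by chance.

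Of 226 small noncoding RNAs, 12 were called higher and 1 lower in supplemented Ts65Dn than in supplemented 2N libraries. The median log2 fold change over the 226 was 4.18, and the class as a whole was not tested. Bc1 in control-diet Ts65Dn 3 stood far from its group at 13.91 log2 CPM (others 4.52 to 6.61). In a score over these RNAs, 5 Ts65Dn libraries lay below the highest 2N library (−0.05). Of these, control-diet Ts65Dn 1, 2 and 5 (−0.83, −0.77 and −0.82) argue against trisomy on its own as the whole cause. The others are supplemented Ts65Dn 2 and 5 (−1.13 and −0.78), whose place in the series table leaves their genotype in doubt. Trisomy together with the supplemented diet therefore stays open. Library depth met the condition set for it, with a within-group r of −0.60 (permutation p = 0.014, adjusted p = 0.032 over 3 relations; rho −0.50, permutation p = 0.033; r −0.64 within group and ID prefix). That relation weakens to r = −0.38 without the 2 libraries farthest in depth, and supplemented Ts65Dn 3 and 8, with 10926756 and 11255859 counts, score 1.78 and 2.12, above all 2N libraries, so depth may be only part of it. The mitochondrial rRNA share stays open, since the median was 1.96 with it as a covariate and the relation had r = 0.60 (permutation p = 0.021, adjusted p = 0.032; rho 0.36, permutation p = 0.15; 0.70 without the 2 farthest; 0.46 within group and prefix).

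Protein-coding genes lower in supplemented than in control-diet Ts65Dn numbered 14 (median −2.03). The low-complexity libraries as the whole cause are argued against by a median of −1.68 without them. That test is weak, because the 14 genes were called in the same contrast and mostly from the same libraries, which favours a low median. It also kept control-diet Ts65Dn 1 and supplemented Ts65Dn 5, where nearly as few genes were detected. RNA of neighbouring glutamatergic neurons may contribute, since 12 soma genes of such neurons had a median of −1.07, which met the condition set beforehand, with 9 negative, a range of −5.46 to 3.45 and 0 called. A glial RNA share stays open: with the glial marker score as a covariate the median was −1.06, below the bound of −1 set for it by less than the spread of these genes. A diet effect in the captured neurons stays among the explanations, untested apart from these.

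Supplemented Ts65Dn 2 and 5 had mitochondrial rRNA shares of 17.8% and 21.2%, below the other 6 of their group. Depth is argued against, since 2 other libraries of the group had totals at or above both with a higher share, and so is the ID prefix, since another library of prefix 15 reached 34.6%. A mislabelled genotype cannot be told apart: the series table lists the 2 among the supplemented 2N samples, which would give the 6 per group of the design text, and over all 75 triplicated genes the index of 5 (−0.217) lay within supplemented 2N (−0.576 to −0.150) and that of 2 (0.214) above it. Over abundant genes both (0.02 and 0.23) lay above supplemented 2N (−0.46 to −0.30), but the higher of these exceeded the highest 2N index by only 0.03, less than the spread among control-diet 2N libraries. No biological explanation was tested.

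Mir6236 differed between genotypes in its supplementation contrast by −3.06, as tested by the interaction (−0.89 in Ts65Dn and 2.17 in 2N). The GABAergic score of control-diet 2N 3 was 1.12 (others 0.34 to 0.63). The striatal neuron score of supplemented Ts65Dn 5 was −2.32 (others −0.83 to 0.50). In log2 CPM, Ppm1l was 7.78 in supplemented 2N 4 (others 6.82 to 6.91). Cbll1 was −0.76 in control-diet Ts65Dn 2 (others −2.25 to −1.74). Tmem184c was 6.12 in supplemented Ts65Dn 2 (others 4.31 to 5.10). Rprl2 was 1.46 in supplemented 2N 4 (others −2.25 to −1.67) and 2.29 in control-diet Ts65Dn 6 (others −2.25 to −0.60). The mt-Atp6 gene was 4.46 in supplemented 2N 2 (others −2.25). Kif3a was 8.38 in supplemented 2N 1 (others 7.80 to 7.89). Snora74a was −0.64 in control-diet 2N 4 (others −2.25) and −2.25 in supplemented Ts65Dn 5 (others 3.32 to 8.09). Snora81 was 1.24 in control-diet 2N 4 (others −2.25).

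Gene and list counts were set against 100 splits of the libraries, with the real grouping counted as 1 of them. For genotype on the control diet only the real grouping, 1 of the 100, reached 67 genes (highest other 21). For supplementation in Ts65Dn 2 splits gave as many genes (real 26, highest other 47). For genotype on the supplemented diet 3 did (36, 41). For supplemented Ts65Dn against control-diet 2N 2 did (109, 110). In the last 3 another split gave more genes than the real groups. Such gene counts were uncommon among the splits. Chance is still not excluded for them, because only 100 splits were drawn and the ID prefix and the litter were left out of account. Gene counts as large were more frequent for supplementation in 2N (10 splits, 1, 1) and the interaction (14 splits, 1, 2). For lists, 2 splits gave as many for genotype on the control diet (16, 16), also uncommon. As many lists came more often for supplementation in Ts65Dn (16 splits, 7, 10) and genotype on the supplemented diet (12 splits, 6, 12). For supplementation in 2N, with 0 lists called, all 100 splits gave as many (highest other 4).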

How the results depend on the processing

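Tests that left out low-complexity libraries or supplemented Ts65Dn 2 and 5, kept 1 ID prefix or protein-coding genes, used the mitochondrial rRNA share or a glutamatergic score as covariate, or used abundant triplicated genes were chosen after the results were seen. Gene counts are given in the order genotype on the control diet (67), supplementation in Ts65Dn (26), supplementation in 2N (1), genotype on the supplemented diet (36), supplemented Ts65Dn against control-diet 2N (109) and the interaction (1), and comparisons not named stayed within 1.5 times. Unless stated, the cause was not tested.

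At an unadjusted p under 0.05 the counts were 2179, 1920, 1382, 1894, 1831 and 1683, and at an adjusted p under 0.1 they were 116, 53, 2 and 57 for the first 4 and 2 for the interaction, by the looser threshold itself. DESeq2's Wald test gave 459, 349, 286, 542, 470 and 366, and limma-voom 3, 4, 7, 55, 302 and 0 (1707 at an unadjusted p under 0.05). The robust fit in edgeR gave 22, 13, 0, 0, 36 and 0, with 1369, 1867 and 1687 at an unadjusted p under 0.05 where it gave 0. Without a filter the counts were 256, 218, 33, 200, 256 and 125, and with at least 1 CPM in 6 libraries 44 for genotype on the control diet. Fits of the compared groups alone gave 3, 6, 2 and 91 for the first 4. The surrogate variable gave 2 and 87 for the first 2, then 15, 52 and 7 for the last 3. The ID prefix as a factor gave 28, 15 and, for the interaction, 12. Prefix 17 alone gave 0 for genotype on the control diet (edgeR, 915 at an unadjusted p under 0.05), and prefix 16 alone 103 for supplementation in Ts65Dn and 92 for genotype on the supplemented diet, with fewer libraries.

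The glial marker score as covariate gave 1 for genotype on the control diet, 63 for genotype on the supplemented diet, 61 for supplemented Ts65Dn against control-diet 2N and 23 for the interaction. Without libraries on the other genotype's side of the dosage midpoint the counts were 9, 125, 111 for genotype on the supplemented diet and 22 for the interaction. Without the low-complexity libraries they were 4, 77, 2, 62 and, for the interaction, 11. Without supplemented Ts65Dn 2 and 5 they were 69 for supplementation in Ts65Dn, then 2, 150, 228 and 24. The mitochondrial rRNA share as covariate gave 162, 59, 3, 0, 28 and 0, with 1158 and 1753 at an unadjusted p under 0.05 where edgeR gave 0. The glutamatergic score gave 21 and 11 for the first 2. Protein-coding genes alone gave 0, 0, 3 and 0 for the last 4, with 678, 933 and 885 at an unadjusted p under 0.05 beside the zeros.

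Lists called with an estimated correlation were 0, 0 and, for genotype on the supplemented diet, 2. With fry they were 9 for genotype on the control diet and 3 for genotype on the supplemented diet. The glial covariate gave 1, 2 and 3 lists for the first 3 comparisons, and the ID prefix as a factor 4 in 2N. Directions reversed under the glial covariate for Bc1 (−1.34), Nptxr (−0.72) and Shank1 (−0.07) of genotype on the control diet. As signed −log10 p, lists that reversed under it were DNA and histone methylation (−0.127), oxidative phosphorylation (0.409), ribosomal proteins (1.88) and oligodendrocytes (2.13) in that comparison and oligodendrocytes (−0.444) for supplementation in Ts65Dn. The covariate is built from the oligodendrocyte and astrocyte markers, so it cannot test either of those lists. Ddn (0.10) and Adcy1 (0.17) reversed within prefix 16, and mt-Rnr2 (−0.06) with the mitochondrial rRNA share, which contains it. The dosage index on the control diet passed over abundant genes (0.378, 0.304 and 0.397 at the 3 floors, and 0.379 without low-complexity libraries), and on the supplemented diet it was −0.1 on log2 TPM and 0.609 within prefix 16, where 2 against 2 libraries cannot pass. Marker scores called fell from 4 to 1 with medians. The correlation of contrasts was −0.035 with the shared libraries split, −0.055 with genes chosen in 1 set of libraries and compared in the other, and −0.604 over protein-coding genes.

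Leaving out 1 library gave 4 to 127, 12 to 80, 0 to 2, 0 to 72, 75 to 154 and 1 to 12 genes, and 11 to 17, 5 to 11, 0 to 1 and 6 to 9 lists for the first 4. The dosage index ran from 0.048 to 0.286 and from 0.49 to 0.632, and the correlation of contrasts from −0.577 to −0.462. Among the other results on named genes, 1313 kept direction and call, 624 lost the call and 6 reversed; among lists these numbered 512, 93 and 5. Small effects could rarely be called, as seen in simulated data with effects of 1 on the log2 scale planted in abundant genes. There 3% were recovered for genotype on the control diet and for supplementation in Ts65Dn, and 0% for supplementation in 2N. Less abundant genes were not tried. Recomputing from per-sample counts was not run because they equal the series table.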

Other observations

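Tests of dendritic transcripts and of the prefix 16 and glutamatergic score alternatives were chosen after the results were seen.

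In a list of 18 dendritic transcripts written after the falling genes were seen, 17 were negative for supplementation in Ts65Dn (median −0.77). Only 3 passed, all 3 among the 14 protein-coding genes that prompted the list, and the other 15 did not, so no change of the group is claimed. The median of the 14 genes was −1.13 within ID prefix 16 and −1.31 with the glutamatergic score as a covariate. Slc17a7, the vesicular glutamate transporter of cortical neurons, was at −4.98 (edgeR, adjusted p = 0.0661). Emx1, Neurod2, Neurod6 and Nrn1 were at −5.46, −4.94, −3.23 and −2.46, and none of these genes passed. Cux2 and Bcl11b, cortical transcription factors, were at 0.28 and −0.65, and Slc17a6 and Neurod1 were at 0.77 and 3.45.

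Striatal neuron markers had 9 of 10 negative for supplementation in Ts65Dn (median −0.64), with Pdyn, the dynorphin precursor, at −6.50 (adjusted p = 0.219), and Penk, the enkephalin precursor, was at −1.34 for genotype on the supplemented diet (adjusted p = 0.21); neither passed. Vascular markers had 13 of 15 positive in supplemented Ts65Dn against control-diet 2N (median 0.52, adjusted p = 0.0755).

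The hypothesis that Lars2 and Mir6236, which both rose in control-diet Ts65Dn, draw on a shared source of reads was tested by their correlation within groups. It gave r = −0.05 (permutation p = 0.83, adjusted p = 0.83; rho −0.16, permutation p = 0.48; −0.25 without the 2 farthest libraries; 0.29 within group and ID prefix). This argues against a shared source that varies between libraries of the same group. Group means were subtracted, so the rise that both genes share between groups was not tested, and a shared source of that rise stays open.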
